A study of Drosophila melanogaster with 2 samples.

How the data were processed

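The data were peak lists from chromatin immunoprecipitation followed by sequencing (ChIP-seq) of Hr51 in whole Drosophila melanogaster embryos of both sexes, aged 14 to 16 h. Hr51, also called unfulfilled, is a nuclear receptor of the NR2E group. The flies carried a transgene that makes Hr51 fused to enhanced green fluorescent protein (eGFP), and the immunoprecipitation used an antibody against GFP, per the labels. Chromatin was sonicated to fragments of 200 to 800 bp, per the labels. There were 2 samples in 1 group, given in the labels as biological replicates 1 and 3 of the same experiment. No second group was used here, so no contrast between conditions was made; the comparisons are between replicates, between peaks and random places, and between classes of genes and sequence.

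Each replicate had 1 deposited peak list, and 2 further deposited lists covered both replicates together: 1 of peaks called on pooled reads and 1 of peaks kept by an irreproducible discovery rate (IDR) procedure, called reproducible peaks below. Coordinates are on dm6, per the labels. The aligner, the peak caller and its settings were not given in the sources used here. The column that ranks peaks holds a score per peak deposited by the authors, called signal below; its scale was not given in the sources used here, so it was used to describe and rank peaks within a list and, on a log2 scale, to correlate the replicates and to compare promoter peaks between groups of genes within the reproducible list. A second column holds, per the file format, the −log10 of a q-value deposited by the authors for each peak; it reached a ceiling of 4.25 in 7229 of 7229 reproducible peaks and was not used in any test. Another column gives the summit, the position of highest signal in each peak. Read counts and sequencing depth were not used here, so depth is unknown and no precision could be attached to a single peak's signal. Intervals given for shares cover counting error over peaks or genes only.

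The replicate and pooled lists each held 30000 peaks, a round number that marks a limit in the calling and not a threshold on the data. The −log10 q-value was at its list's highest value in 28.2% of replicate 1, 28.1% of replicate 3 and 29.6% of pooled peaks. It went down to 0.538, 0.403 and 0.433, so these lists also hold weak calls. Whole-list overlaps, X ratios over all 30000 peaks and counts within 20 kb of Hr51 include them. All 7229 reproducible peaks were found in the pooled list with the same coordinates and signal, and they were the 7229 pooled peaks of highest signal. Taking as many of the highest pooled peaks, listed before the data were seen as a check, therefore gave the same list and tested nothing. Some rows share an interval and differ in summit: the 7229 reproducible summits lay in 7157 distinct intervals. Each summit was counted.

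Genes and transcription start sites (TSSs) came from the Ensembl annotation of the same chromosome sequences, and DNA came from the reference genome of the same release. The 13945 protein-coding genes on chromosome arms 2L, 2R, 3L and 3R and on chromosomes 4 and X formed the background. No list had a peak on another chromosome or scaffold. A promoter peak was a summit within 1000 bp of a TSS of the gene. Summits were put in classes in the order promoter, 5' UTR, coding sequence, 3' UTR, noncoding exon, intron and intergenic.

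Replicates were compared by overlap of at least 1 bp, against 100 placements of the same peaks at random on the same chromosomes. Signal was compared over reproducible peaks that overlap a peak in both replicates, each matched to the peak with the nearest summit, by Pearson's r on log2 signal and by Spearman's rho. These are correlations across peaks of 2 libraries; peaks are not independent replicates, so no p-value was given. The share of summits near TSSs was compared with 1000 random placements on the same chromosomes (two-sided empirical p, smallest value 0.0020). Peak density on X and on the other chromosome arms (2L, 2R, 3L and 3R) was compared with an exact binomial test, two-sided. For 20 gene lists, the share of members with a promoter peak was compared with that of all other protein-coding genes by Fisher's exact test, two-sided. The log2 signal of the strongest promoter peak was compared by a permutation test with 100000 resamples for lists with at least 5 such genes. For 15 sequence motifs and 2080 6-mers counted on both strands, the windows from 50 bp upstream to 50 bp downstream of each summit were compared with windows of the same width centred 300 bp away, on a side drawn at random, by the exact McNemar test, two-sided. All p-values within a family were adjusted by the Benjamini-Hochberg method. A threshold of 0.05 on the adjusted p was used.

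The gene lists, the motifs, the tests and the rule for named genes were fixed before the data were examined. The rule takes the 10 reproducible peaks of highest signal; Hr51, EcR, per, tim, Clk, cyc, vri, Pdp1, Fas2 and all other nuclear receptors; up to 4 members of each list with the highest promoter signal; and the 10 protein-coding genes with the most reproducible summits in the gene with 1 kb on each side. A gene that this rule takes from the ribosomal protein list is not reported here. Of the names written for the lists, phm, EcI, dumpy, Dl and Hpo did not match a symbol. The chorion list was written as a symbol pattern and also took Cp110 and Cp190, which are not eggshell genes, and the proteasome pattern also took paralogs named with R or T. Both lists were tested again without these. The 20 lists share some members, such as nuclear receptors that also belong to the ecdysone list.

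For each replicate alone, the 7229 peaks of highest signal stood in for the reproducible list, which gives each result without replicate 1 and without replicate 3. Other alternatives changed the distance to a TSS, the window and the control sequence for motifs, the random placement, the assignment of peaks to genes, and the peaks kept (3614 of highest signal). For motifs and 6-mers, a window of the same GC content means the nearby window closest in GC to the summit window. Any GC difference left was not measured. Random gene lists were also drawn 10000 times with the same number of TSSs and similar gene lengths (smallest p 0.00020), for promoter peaks only. The functions for overlap, the TSS share, the X ratio, gene lists, matched lists, promoter signal, motifs and 6-mers were tested on simulated data first. Those for replicate correlation, location classes, GC content, peak density and the GC-matched and shuffled controls were not. With 4 of 20 lists of 40 genes given shares of 60% against 23% among 13945 genes, 4 of 4 were called and 0 of the 16 others. A site written into 10% of 7229 simulated windows, 9.47 percentage points beyond chance, came out 9.50 percentage points above the control. Smaller differences in shares or sites were not simulated. A rise of 1 in the log2 signal of 30 genes was called and came out as 0.646, since these genes differed from the others by -0.354 before the rise. With nothing written in, 0 of 2080 6-mers were called. The simulated summits for motifs and 6-mers lay at random places, with no difference in base composition built in. They therefore do not show how often these tests call sites at AT-rich summits. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and, for figures, matplotlib 3.10.9.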

Results

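Binding of Hr51 was measured by ChIP-seq in whole embryos aged 14 to 16 h, late in embryonic development, when the nervous system and most organs have formed. The 2 samples, biological replicates 1 and 3, each gave a list of 30000 peaks. The list of reproducible peaks held 7229 peaks with a signal, the authors' score for each peak, from 135 to 5850 (median 270). Depth is unknown. The values of each replicate stand beside the main ones as a measure of replicate spread, and replicate lists cut to the highest 7229 peaks are used where the number of peaks matters.

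The strongest reproducible peaks ranked high in both replicates. They were picked by a signal from the pooled reads of both replicates, so high ranks in each are in part built in. Peaks beside or inside CG11050, cbt, CG14100, mRpL41, Ugalt, lncRNA:CR44619, SLC5A11, Trl, CG18549 and Gapdh2 led the reproducible list, and 10 of these 10 peaks ranked among the highest 15 of replicate 1 and among the highest 15 of replicate 3. Over the whole lists, 76.4% of the 30000 replicate 1 peaks overlapped a replicate 3 peak (95% Wilson interval 75.9 to 76.9%), against 15.6% ± 0.198 (SD over 100 placements) for peaks placed at random. In the other direction 70.0% overlapped (69.5 to 70.5%), against 14.7% ± 0.197. With both lists cut to their top 1000 peaks, 86.2% (83.9 to 88.2%) of those of replicate 1 overlapped a peak among those of replicate 3. In the other direction 85.0% (82.7 to 87.1%) overlapped, with 0.540% and 0.582% for random places. Overlap of the top 1000 peaks with the whole list of the other replicate was not computed. When summits had to lie within 100 bp of each other, the whole-list share was 51.8% in both directions. Of the 7229 reproducible peaks, 7036 (97.3%) overlapped a peak in both replicates. The reproducible peaks came from an IDR procedure on these same replicates and were the pooled peaks of highest signal. A high share is therefore in part built in, and the name does not mean that each peak was found in both replicates. The overlap of the replicates' own lists does not rest on that choice. Across the 7036 peaks the replicate signals had a Pearson's r of 0.863 on the log2 scale and a Spearman's rho of 0.818. Both describe peaks selected from these 2 libraries and not independent replicates.

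**Figure D1:**
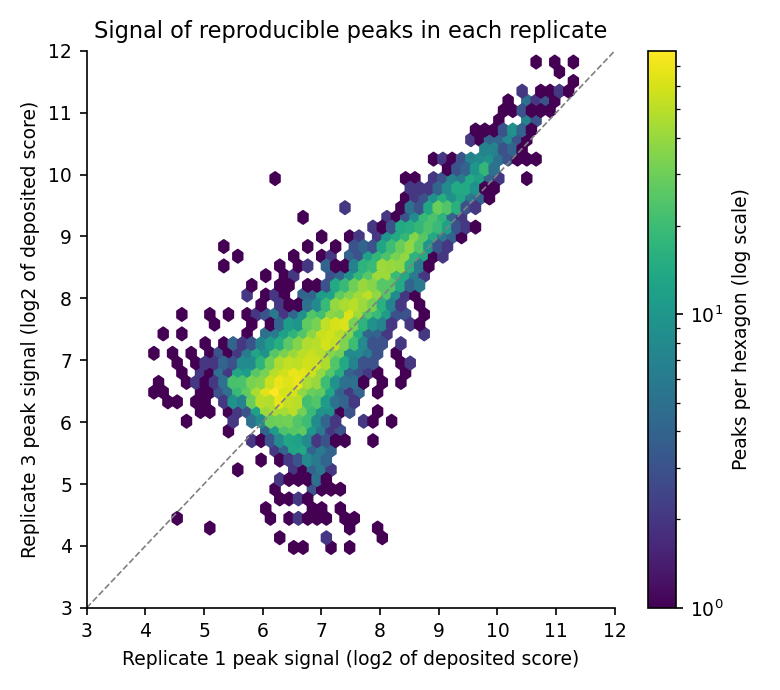
Each hexagon counts reproducible peaks (colour, log scale) by their signal in replicate 1 (x axis) and replicate 3 (y axis), both as log2 of the deposited score; the dashed line marks equal scores. The 7036 peaks lie along a rising band (Spearman's rho 0.818) that is tightest among the strongest peaks.

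The strongest reproducible peak lay on 2L from 6612387 to 6612952 (dm6) in an intron of CG11050, with its summit 1022 bp downstream of the nearest TSS and a signal of 5850. It ranked 1 in replicate 1 and 3 in replicate 3. The next (2L, 480530 to 481420, signal 5508) lay in an intron of ush, which encodes a zinc-finger cofactor of GATA factors, 1369 bp upstream of the TSS of cbt, a gene for a zinc-finger transcription factor. The peak at Trl (3L, 14759242 to 14759783, signal 4749), which encodes the GAGA factor, was also intronic, 1524 bp downstream of a TSS. The other 7 had a TSS within 1 kb. The summit at CG14100 (3L, 19590388 to 19590834, signal 5498) was 89 bp upstream of its TSS. At mRpL41, a mitochondrial ribosomal protein gene (2R, 15217559 to 15218013, signal 5263), it was 141 bp upstream, and TSSs of CG8079 and lncRNA:CR44463 also lay within 1 kb. The peak at Ugalt, a UDP-galactose transporter gene (X, 2703640 to 2704110, signal 5238), lay between it and eIF2Bbeta. The peak at lncRNA:CR44619 (X, 12750760 to 12751678, signal 4955) had its summit in an exon of the noncoding gene lncRNA:Vinr. At SLC5A11 (2L, 8205041 to 8205531, signal 4916) the summit fell in an exon of the noncoding gene asRNA:CR44119. The peaks at CG18549 (3R, 12448935 to 12449377, signal 4564) and at Gapdh2, a glycolytic gene (X, 15867731 to 15868222, signal 4325), lay 137 and 164 bp upstream of the TSS, in intergenic DNA.

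Promoters and introns held most Hr51 summits, and coding sequence held almost none. Of the 7229 reproducible summits, 3364 lay within 1 kb of a TSS (46.5%, 95% Wilson interval 45.4 to 47.7%), 1.97 times the 23.6% of random places on the same chromosomes (permutation of positions, p = 0.0020, the smallest value that 1000 placements can give). The share was 49.6% among the highest 7229 peaks of replicate 1 and 47.2% among those of replicate 3. Random places 2 to 10 kb from each summit, chosen after the data were seen, had a share of 29.4%. Against these the ratio was lower, at 1.58. Coding sequence outside promoters held 8 summits (0.111%), against 10.4% of random places, 3' UTRs held 55 (0.761%, against 3.73%) and intergenic DNA held 1053 (14.6%, against 25.03%). These shares were lower than random placement in each case (adjusted permutation p = 0.0028). The 5' UTRs held 13 (0.180%, against 0.451%) and were also lower, and noncoding exons held 48 (0.664%, against 0.471%) and were higher (adjusted permutation p = 0.0028 and 0.026). Introns held 2688 summits (37.2%), against 36.3% of random places (adjusted permutation p = 0.110), but promoters are counted first and take more of the summits than of random places. Among the 3865 summits outside promoters, a comparison chosen after the data were seen, introns held 69.5%, against 47.5% of random places outside promoters (adjusted permutation p = 0.0024). The coding share was 0.138% in replicate 1 and 0.124% in replicate 3. Against random places chosen after the data were seen to match the GC content of the 51 bp at each summit, of which 3.17% were coding, the observed share was still lower by 28.6 times (permutation p = 0.0020).

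Near promoters, summits sat upstream of the start site. Of the 3364 summits within 1 kb of a TSS, 2447 (72.7%) were upstream, and 1610 (47.9%) fell in the 300 bp just upstream, with a median position of -140 bp from the TSS, negative meaning upstream. The upstream share was 70.0% in replicate 1 and 74.3% in replicate 3.

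**Figure D2:**
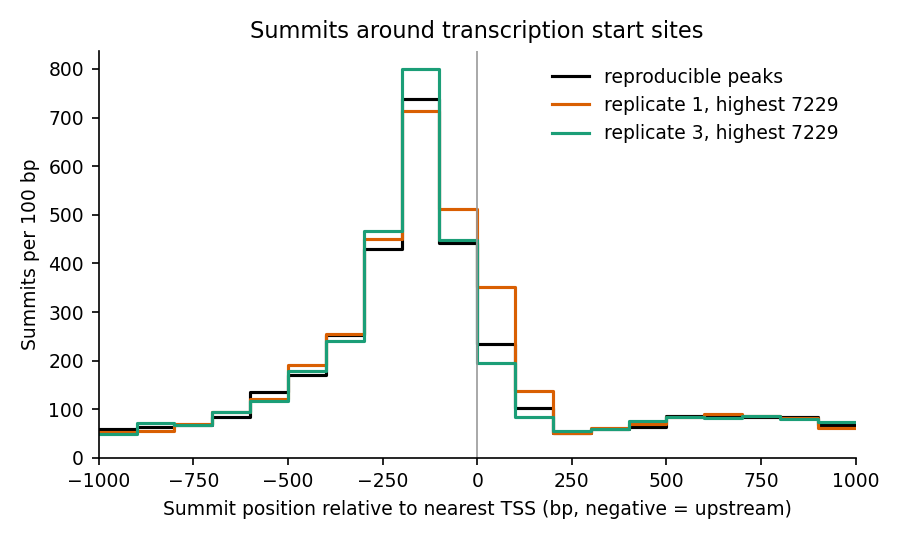
Summits per 100 bp (y axis) by position relative to the nearest TSS in bp (x axis, upstream negative), for reproducible peaks and for the highest 7229 peaks of each replicate. All 3 lists have their highest bin from 200 to 100 bp upstream of the TSS, with 738 reproducible summits.

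Chromosome X carried somewhat more Hr51 peaks per Mb than the large autosome arms, which also differed among themselves. X held 1446 reproducible summits, 61.6 per Mb, and 2L, 2R, 3L and 3R together held 5775, or 53.1 per Mb, a ratio of 1.16 (95% exact interval 1.10 to 1.23, exact binomial p = 6.0e-07, two-sided). By arm the density was 57.2 per Mb on 3L, 55.3 on 2L, 52.1 on 3R and 47.7 on 2R, so X had 1.08 times the density of 3L, while 3L had 1.198 times that of 2R. The exact test treats peaks as independent and does not cover this spread between arms. Over all 30000 peaks X hardly exceeded the densest arm, by 1.02 times in replicate 1 and 1.003 times in replicate 3, and the ratio to the 4 arms together was 1.07 and 1.08. That ratio was 1.12 for the highest 7229 peaks of replicate 1 and 1.15 for those of replicate 3. Per TSS the ratio was 1.25 (1.18 to 1.32, exact binomial p = 1.5e-13). Chromosome 4 held 8 summits, 6.01 per Mb, and no list had a peak on Y. The embryos were of mixed sex, so X was present in fewer copies than the autosomes; no copy-number adjustment was made.

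Ribosomal protein genes stood out among the gene groups with a promoter peak, and chemoreceptor genes among those without. Of 13945 protein-coding genes, 3247 (23.3%) had a promoter peak. Cytoplasmic ribosomal protein genes had one in 58 of 82 cases (70.7%), against 23.004% of other genes (log2 odds ratio 3.00, Fisher's exact test with Benjamini-Hochberg adjustment over 20 lists, adjusted p = 1.8e-18), with 62 in replicate 1 and 65 in replicate 3. Strong promoter peaks in this list were at RpL34b (signal 1164), RpS27 (1003) and RpL7 (816), with summits 143, 0 and 24 bp from a TSS of the gene. Chemoreceptor genes, which serve sensory neurons and were listed as a group not expected to be active at this stage, had a promoter peak in 1 of 119 cases (0.840%, log2 odds ratio -4.60, exact adjusted p = 1.2e-11), with 2 in each replicate. The exception was Or88a, with a signal of 1166 and a summit 625 bp from its TSS. Both differences also held against random lists of genes with like numbers of TSSs and lengths, which gave 17.3 and 21.5 genes on average (adjusted permutation p = 0.0020 for both).

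Genes of developmental signalling, of mushroom body and neuron remodelling, and of the nuclear receptor family also had promoter peaks more often than other genes. Signalling genes had them in 21 of 42 cases (log2 odds ratio 1.73, exact adjusted p = 0.0010), led by spi, which encodes an EGF receptor ligand (signal 1686), brk, a repressor of Dpp target genes (1510), nkd, an antagonist of Wnt signalling (1226), and aos, an inhibitor of the EGF receptor (1126). Remodelling genes had them in 14 of 26 cases (log2 odds ratio 1.94, exact adjusted p = 0.0036), led by dnc, a cAMP phosphodiesterase gene needed for memory (2171), Sox14, a transcription factor of neuron pruning (2073), Eip75B (1540) and Hr51 itself (1227). Nuclear receptors had them in 11 of 21 cases (log2 odds ratio 1.85, exact adjusted p = 0.014). The counts in replicates 1 and 3 were 21 and 19, 14 and 13, and 12 and 11. Against lists matched on TSS number and gene length, which gave on average 15.4, 11.9 and 8.64 genes, none of these 3 lists passed the test (adjusted permutation p = 0.267, 0.849 and 0.756). Signalling genes also missed the threshold with summits within 500 bp of a TSS (14 of 42, exact adjusted p = 0.090), and remodelling genes in the stronger 3614 peaks (8 of 26, exact adjusted p = 0.166).

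Axon guidance genes had promoter peaks in 17 of 42 cases, which just missed the threshold (exact adjusted p = 0.052). They passed it at 500 bp (exact adjusted p = 0.010), at 2000 bp (0.023), with gene bodies and with nearest-TSS assignment (29 of 42 in both), but not in the highest peaks of replicate 1 (16 of 42, 0.111) or replicate 3 (13 of 42, 0.466) or in the stronger 3614 peaks (9 of 42, 0.569). Matched lists gave 15.7 genes on average for promoter peaks (adjusted permutation p = 0.972). None were drawn for gene bodies or nearest-TSS assignment, for this list or for the clock and ecdysone lists below. The strongest peaks were at the netrin receptor gene unc-5 (signal 2338, rank 40 in replicate 1 and 236 in replicate 3), which lies beside Hr51, and at trio (726), PlexA (679) and Nrt (676). Circadian clock genes had 9 of 21, including sgg (1975), Pdp1 (1419), vri (921) and cry (398), and ecdysone pathway genes had 9 of 22, including tai (672), ftz-f1 (474) and Eip63E (289); both had an exact adjusted p of 0.181. Clock genes passed the threshold at 500 bp (9 of 21, exact adjusted p = 0.042) and with nearest-TSS assignment (11 of 21, 0.024), and ecdysone genes with gene bodies (14 of 22, 0.0047) and nearest-TSS assignment (13 of 22, 0.0033). Against matched lists, with 7.92 and 9.74 genes on average, neither passed the test (adjusted permutation p = 0.972 and 1). The reproducible peaks at cry and PlexA overlapped no replicate 1 peak. Pan-neural and synaptic genes had 12 of 39, with elav, a marker of neurons, at 2347, Nrx-1 at 1494, Nlg2 at 537 and scrt at 484. Glial genes had 7 of 22, with Gs2 at 1070, moody at 1057, Gli at 605 and htl at 561. Muscle genes had 10 of 31, with Msp300 at 1930, sls at 1111, tin at 991 and Act87E at 603. Gut and endoderm genes had 5 of 15, with bowl at 2027, Hnf4 at 1164, fkh at 266 and GATAe at 239. The exact adjusted p of these 4 lists was between 0.461 and 0.483.

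Neuropeptide genes had promoter peaks in 7 of 32 cases, with ITP at 772, amn at 482, Proc at 400.9 and sNPF at 388 (exact adjusted p = 1). Neuron identity factors had 7 of 40, with lola at 1091, fru at 407, sqz at 369 and Lim1 at 235 (exact adjusted p = 0.572). Neuroblast genes had 4 of 30, namely brat (1800), numb (1651), grh (427) and da (248), with an exact adjusted p of 0.461; the da peak overlapped no replicate 3 peak. Genes of epidermis, cuticle and trachea had 5 of 28, with trh at 1143, mmy at 604 and Ddc at 270 (exact adjusted p = 0.728). Fat body and hemocyte genes had 3 of 18, namely Adh (619), ush (223) and vkg (136), with an exact adjusted p of 0.821. Proteasome subunit genes had 9 of 48, with Prosbeta7 at 720, Rpn3 at 630, Rpn13 at 383 and Rpn5 at 382 (exact adjusted p = 0.715), and 9 of 32 without the paralogs named R or T. Hox genes had 0 of 8 (Fisher's exact test, adjusted p = 0.461), while 6 of the 8 had a summit in the gene with 1 kb on each side and 7 were the nearest gene of a summit, both more often than other genes (exact adjusted p = 0.030 and 0.0017). The chorion list had 1 of 13 (exact adjusted p = 0.461), and that gene was Cp190, an insulator protein gene (2145); without Cp190 and Cp110 it had 0 of 11. Against matched lists, neuron identity factors had fewer promoter peaks than the 14.9 genes drawn on average (adjusted permutation p = 0.041). Against all other genes the promoter share, 17.5% against 23.3%, did not pass the threshold (exact adjusted p = 0.572). By nearest gene the direction turned, with 23 of the 40 nearest to a summit (57.5% against 26.5% of other genes, exact adjusted p = 2.0e-04). With 1 kb on each side of the gene, 18 of the 40 had a summit (30.4% of other genes did, exact adjusted p = 0.114). No matched lists were drawn for these 2 assignments, so these counts and those of Hox genes take no account of gene length.

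**Figure D3:**
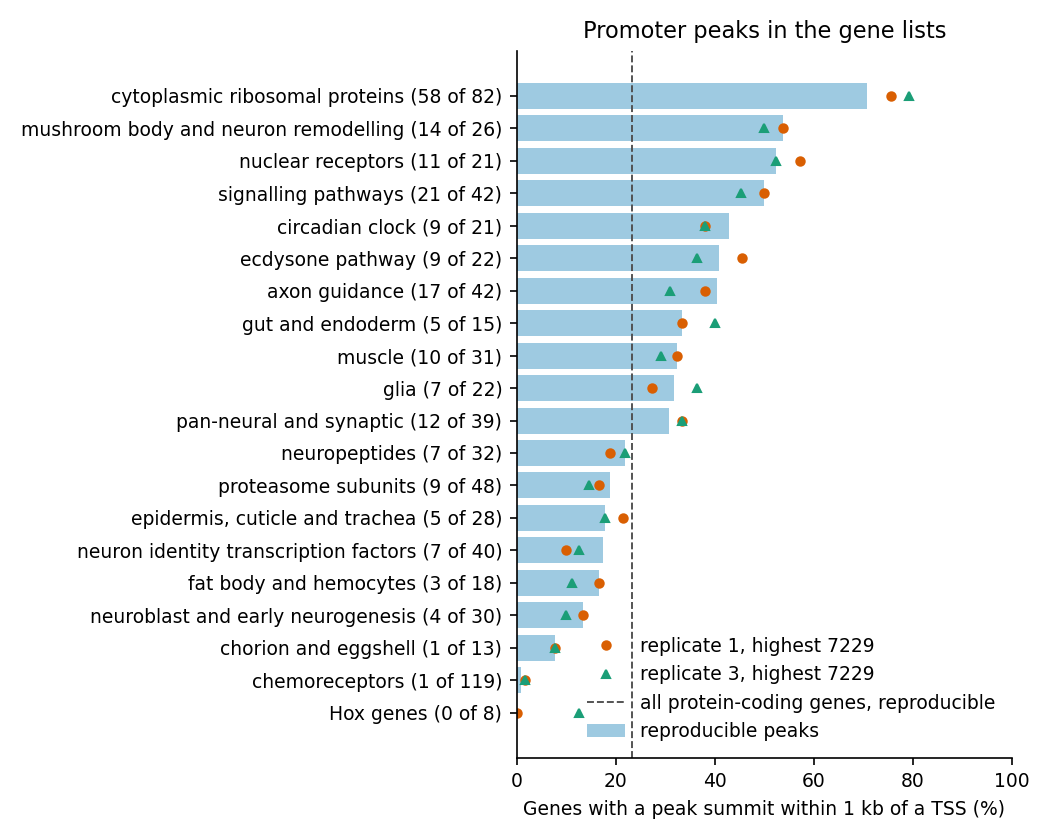
Bars show the share of genes in each of 20 lists (counts beside the names) with a reproducible summit within 1 kb of a TSS, in percent; circles and triangles show the same for the highest 7229 peaks of replicates 1 and 3, and the dashed line marks all protein-coding genes (23.3%). Cytoplasmic ribosomal proteins reach 70.7% and chemoreceptors 0.840%.

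Hr51 peaks lay at the Hr51 gene itself. The Hr51 gene (FBgn0034012, 2R, 15331325 to 15339384) had 6 reproducible summits in the gene and the 1 kb on each side. The strongest pair shared the interval from 15330381 to 15331446, with summits 570 and 369 bp upstream of the TSS in an exon of the noncoding gene lncRNA:CR44371 and signals of 1227 and 588. The stronger of these ranked 248 in replicate 1 and 642 in replicate 3. Another peak of signal 878 (15339475 to 15339852) lay just downstream of the gene, and 3 weaker peaks with signals from 144 to 256.01 were intronic. All 6 overlapped peaks in both replicates.

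**Figure D4:**
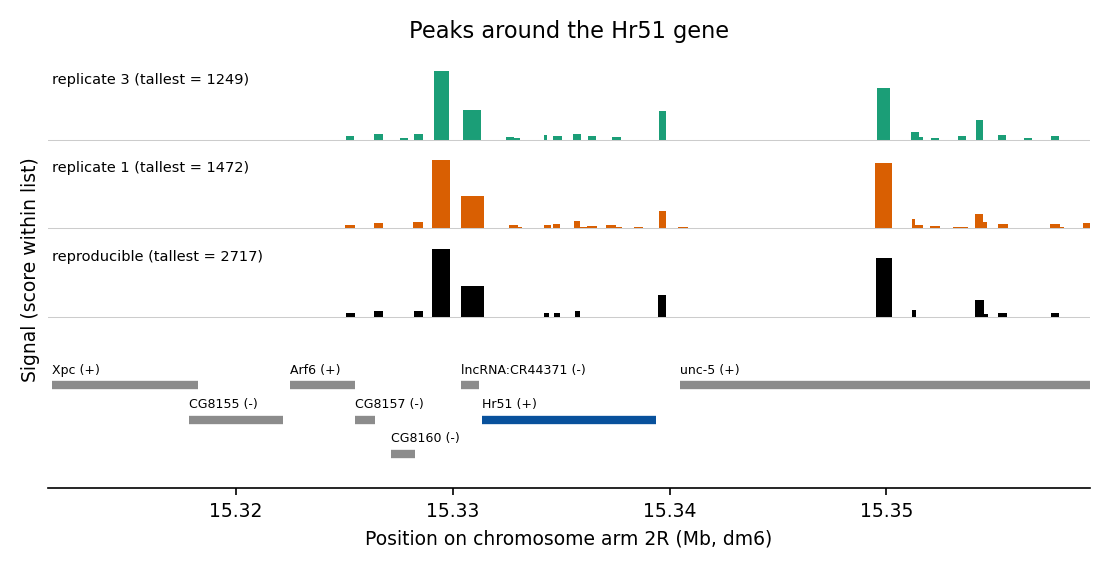
Peaks within 20 kb of the Hr51 gene on 2R (x axis, position in Mb, dm6), as boxes whose height is the signal relative to the tallest peak of each track (2717 for reproducible peaks); bars below mark annotated genes with their strand. The Hr51 promoter peaks, a taller peak upstream and the peak inside unc-5 (signal 2338) appear in both replicates.

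Of the 28 genes named in advance (Hr51, EcR, clock genes, Fas2 and the other nuclear receptors), 15 had a promoter peak, 3 had peaks only elsewhere in the gene or within 1 kb of it, and 10 had neither. EcR, the ecdysone receptor gene (2R), had 1 promoter peak, in an intron from 6157091 to 6157616, with a signal of 269. With 1 kb on each side, EcR held 7 summits. Its partner usp (X) had peaks of 277 and 189. Among clock genes, vri (2L, 5299265 to 5299628, signal 921) and Pdp1 (3L, 7855684 to 7856238, signal 1419) had intronic peaks near internal TSSs. Pdp1 had 4 more promoter peaks with signals from 155 to 189, in 5' UTR, intron and intergenic DNA. The peak at tim (2L, 3506794 to 3507203) was weak, with a signal of 150, and ranked 15206 in replicate 1 and 5056 in replicate 3. The genes per, Clk and cyc had no reproducible peak in the gene or within 1 kb. Fas2, a cell adhesion gene (X, 4205740 to 4205912), had a promoter peak of signal 204. Eip75B (3L, 17999560 to 17999993, 5' UTR) reached 1540, with 2 further promoter peaks of 204 and 166. Hnf4 had promoter peaks of 1164, 240 and 217, Hr78 had 1 of 1025, Hr96 had 1 of 934, ERR had 562 and 346, ftz-f1 had 474, Hr38 had 340 and Hr39 had 139. With 1 kb on each side of the gene, ftz-f1 held 16 summits (strongest 1115), Pdp1 15, Eip75B 11, Fas2 4 and vri 3. Hr3 (2R, strongest peak 10219776 to 10220313, signal 2910), Hr4 (X, 1963752 to 1964148, signal 1292) and Eip78C (3L, 21253796 to 21254034, signal 411) had no promoter peak but had 7, 9 and 3 summits in the gene or within 1 kb. Hr83, dsf, eg, kni, knrl, svp and tll had none.

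Long genes collected the most summits. The gene kirre, which encodes an adhesion protein of myoblast fusion and covers 394149 bp of X, held 34 reproducible summits with 1 kb on each side included, or 0.858 per 10 kb of that stretch against 0.541 over the chromosomes. CG1677 held 21, Ten-a 19, rdx 18, shn 18, Snoo 17, ush 17, CG32264 16, ftz-f1 16 and fz2 16. The densest of these were ftz-f1 with 3.04 and shn with 2.98 per 10 kb. Summits were counted by position, so the count of CG1677 takes in the promoter peak of brk, a gene that lies inside it.

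Promoter peak strength did not separate the gene lists. Mean log2 signal of the strongest promoter peak was 9.15 ± 1.12 (SD) for 11 nuclear receptors, against 8.76 ± 1.16 for other genes with a promoter peak (permutation test, adjusted p = 0.827). It was 8.55 ± 0.781 for 58 ribosomal protein genes, against 8.77 ± 1.16 (adjusted permutation p = 0.590). Of the 15 lists with at least 5 such genes, 0 were higher and 0 lower at an adjusted p under 0.05, and the smallest unadjusted p was 0.126, for proteasome subunits.

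Hr51 summits lay in short stretches of AT-rich DNA. Mean GC content was 30.6% in the 51 bp at the summit, 44.2% at 250 bp away and 41.8% at 1000 bp away. The dip was present within 1 kb of a TSS (31.3% at the summit) and farther away (30.01%), and in replicate 1 (32.2%) and replicate 3 (30.02%). It was deeper in the fifth of reproducible peaks with the highest signal (27.6%) than in the fifth with the lowest (33.9%), and shallow in the 22771 pooled peaks below the reproducible list (39.99%).

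**Figure D5:**
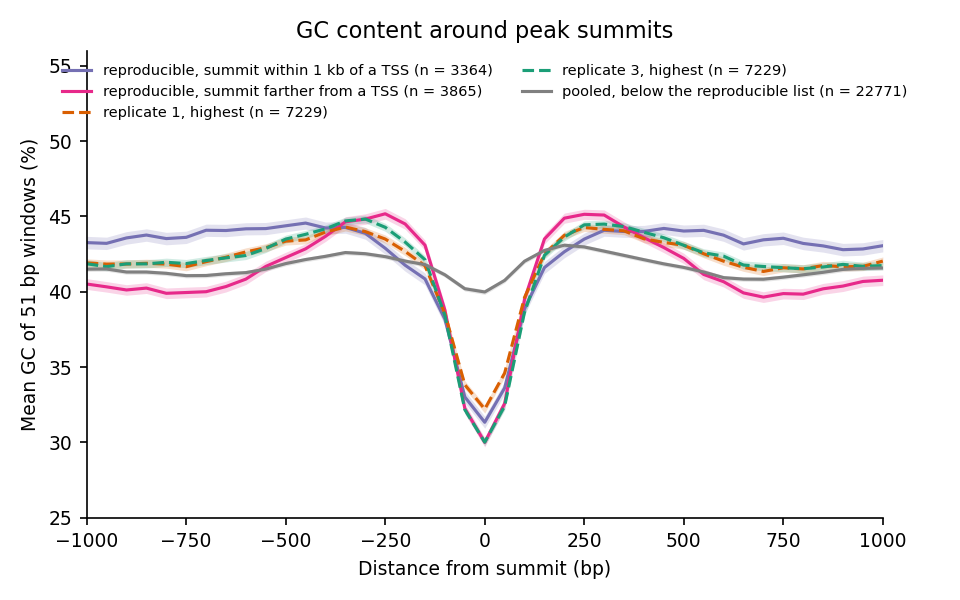
Mean GC content of 51 bp windows in percent (y axis, which does not start at 0) by distance from the summit in bp (x axis); shading marks 95% intervals of the mean. Reproducible peaks near TSSs and farther away and the highest 7229 peaks of each replicate fall to between 30.01 and 32.2% at the summit, and weaker pooled peaks to 39.99%.

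The NR2E half-site, AAGTCA, the sequence that receptors related to Hr51 bind, was found in 5.92% of summit windows and 4.50% of windows 300 bp away (428 and 325 of 7229, exact McNemar test, adjusted p = 3.3e-04). A scrambled control site, ACTAGA, was also more frequent at summits (3.07% against 1.87%, exact adjusted p = 1.0e-05). The half-site was also higher against windows 1000 bp away (5.92% against 4.88%, exact adjusted p = 0.014) and with windows of 100 bp on each side (11.2% against 9.38%, adjusted p = 7.5e-04). It did not pass the threshold against the shuffled summit sequence (exact adjusted p = 0.225), in nearby windows of the same GC content (5.24%, adjusted p = 0.458), in the 3614 strongest peaks (adjusted p = 0.627) or in the highest peaks of replicate 3 alone (adjusted p = 0.531) or replicate 1 alone (adjusted p = 0.138). The direct repeat of the half-site was found in 0 windows, and the general nuclear receptor half-site AGGTCA in 2.14% at the summit and 2.37% away (exact adjusted p = 0.464). The longer site TCAAGGTCA was in 1 summit window and 10 control windows (exact adjusted p = 0.016), too few to rest on. The longer site did not differ from windows 1000 bp away (1 and 3, exact adjusted p = 0.670) or from shuffled sequence (1 and 3, exact adjusted p = 0.721). In nearby windows of the same GC content it also missed the threshold (1 and 5, 0.471), and the highest peaks of replicate 3 had 2 and 1. It stayed lower with 100 bp on each side (7 and 20, exact adjusted p = 0.022), in the 3614 strongest peaks (0 and 6, 0.047) and in the highest peaks of replicate 1 (1 and 11, 0.011).

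Other promoter and insulator sites differed at summits. The core of the CTCF site, an insulator protein's site, was found in 27 summit windows and 6 control windows (0.373% and 0.083%, exact adjusted p = 6.1e-04), and was the only site of 15 still higher against nearby windows of the same GC content (adjusted p = 0.0049). The Dref site TATCGATA (0.678% against 0.249%, exact adjusted p = 3.3e-04), the Ohler 6 promoter element (0.526% against 0.235%, adjusted p = 0.0097) and the homeodomain core TAATTA (12.4% against 5.13%, adjusted p = 2.8e-53) were higher at summits. The Ohler 6 difference missed the threshold in the highest peaks of replicate 3 (exact adjusted p = 0.05005) and replicate 1 (0.060), against windows 1000 bp away (0.072) and against shuffled sequence (0.086), and that of Dref in the stronger 3614 peaks (0.096). Against shuffled summit sequence TAATTA turned to the opposite direction, with -2.13 percentage points (exact adjusted p = 2.2e-04). GAGA (0.913% against 3.40%, exact adjusted p = 2.1e-25), the E-boxes CAGCTG (2.34% against 4.87%, adjusted p = 9.9e-16) and CACGTG (0.498% against 1.62%, adjusted p = 1.3e-10), the grainyhead site (0.180% against 0.539%, adjusted p = 6.8e-04) and the Zelda site (0.290% against 0.567%, adjusted p = 0.019) were lower. The Zelda difference missed the threshold in the highest peaks of replicate 3 (exact adjusted p = 0.155) and replicate 1 (0.126) and against windows 1000 bp away (0.131). Against nearby windows of the same GC content 0 of these 5 lower sites passed the threshold (exact adjusted p from 0.471 to 1), with the grainyhead site in 13 and 13 windows. GAGA and CAGCTG were higher than in shuffled sequence, by 0.526 and 1.37 percentage points (exact adjusted p = 1.5e-04 and 1.1e-09), and CACGTG did not pass the threshold there (36 and 51 windows, exact adjusted p = 0.193). The M1BP site did not differ from windows 300 bp away (18 and 17, exact adjusted p = 1) but was higher than in shuffled sequence (18 and 1, adjusted p = 2.2e-04) and with windows of 100 bp on each side (62 and 33, adjusted p = 0.0039).

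Of 2080 6-mers, 562 were more frequent at summits and 1185 less frequent (exact McNemar test, adjusted p under the threshold of 0.05). AAATAT was in 38.6% of summit windows and 13.8% of control windows, ATATTA in 25.3% and 5.93%, and TTAAAA in 36.5% and 13.04%, while GCGGCA fell from 7.51% in control windows to 1.63% at the summit. All 36 of the 6-mers made of A and T alone were higher, and 36 of the 36 made of G and C alone were lower. Against nearby windows of the same GC content 70 were higher and 59 lower. The leading ones were then ATATTA (25.3% against 20.3%, exact adjusted p = 8.5e-11), ACACTG (4.63% against 2.57%, adjusted p = 2.8e-08) and ACAGTG (4.94% against 2.90%, adjusted p = 1.8e-07).

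No difference in the half-site was found by peak strength or by distance to promoters. AAGTCA was in 5.19% of windows in the highest signal quintile and 6.57% in the lowest (odds ratio 0.778, Fisher's exact test, adjusted p = 0.266), and in 5.59% within 1 kb of a TSS and 6.21% farther away (odds ratio 0.894, adjusted p = 0.272).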

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

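Tests against windows of the same GC content, the shuffled control for 6-mers, random places 2 to 10 kb away or of the same GC content, 1 summit per interval and summits outside promoters were chosen after the data were seen. The TSS share kept its direction and stayed past the threshold in the 8 alternatives that changed a setting (35.2 to 60.2%). It was 35.2% at 500 bp, against 13.5% of random places, and 60.2% at 2000 bp, against 37.8%. Against random places 2 to 10 kb from each summit the ratio fell from 1.97 to 1.58. The X to autosome ratio also kept its direction and threshold in 4 alternatives (1.12 to 1.25). Over all 30000 peaks of replicates 1 and 3 it was 1.07 and 1.08. With ranks or at 500 or 2000 bp, 0 gene lists differed in promoter signal. The low coding share held against both added placements and outside promoters, where the intron share passed the threshold. Taking as many pooled peaks was the same list and tested nothing. The replicate overlap, 76.4 and 70.0% by 1 bp, was 59.9 and 57.4% with a reciprocal 50% and 51.8 and 51.8% with summits within 100 bp. With both lists cut, it was 84.1 and 80.6% between the top 5000 peaks of each and 86.2 and 85.0% between the top 1000. Spearman's rho, 0.818, was 0.833 with summits within 100 bp, 0.843 in the stronger 3614 peaks, 0.846 near TSSs and 0.789 farther away. The number of gene lists above and below other genes, 4 and 1, was 7 above with gene bodies, 9 and 2 with nearest-TSS assignment, and 1 and 2 with matched lists. Matched lists covered promoter peaks only, so the counts with gene bodies and nearest-TSS assignment take no account of gene length. Of 162 values of single lists, without that identical pooled list and with matched lists included, 130 kept their direction and call, 5 lost the call, 10 gained it and 17 turned direction. The log2 ratios that turned were, with gene bodies, Hox genes (2.58, past the threshold), neuron identity factors (0.916) and epidermis (0.158); with nearest-TSS assignment, Hox genes (3.79) and neuron identity factors (1.90), both past the threshold, neuroblast genes (0.286) and epidermis (0.860). Against matched lists they were ecdysone (-0.108), pan-neural (-0.400), glia (-0.177), muscle (-0.271), gut (-0.352) and proteasome (0.0182), and in the stronger 3614 peaks neuropeptides (0.132) and epidermis (0.00887). Glia at 500 bp (-0.000816) and the shorter proteasome list (0.414) also turned. Motifs above and below the control numbered 6 and 6, with 3 below against shuffled sequence; against windows of the same GC content 1 motif was above and 0 below. The excess of AAGTCA, 1.42 percentage points, stayed past the threshold against windows 1000 bp away (1.04) and with 100 bp on each side (1.78) and was no longer past the threshold against shuffled sequence (0.539), in the stronger 3614 peaks (0.304), with 1 replicate left out (0.304 to 0.595) and against windows of the same GC content (0.678). The 562 higher and 1185 lower 6-mers were 70 and 59 against windows of the same GC content and 217 and 314 against shuffled sequence. Motif differences that turned direction were, against shuffled sequence, GAGA (0.526), CAGCTG (1.37), TAATTA (-2.13) and the scrambled site (-0.0692); against windows of the same GC content, AGGTCA (0.277), CAGCTG (0.0968) and the scrambled site (-0.290); in the stronger 3614 peaks, M1BP (-0.166); and TCAAGGTCA, which was 0.0138 without replicate 1 and -0.138 without replicate 3. Apart from base composition, the cause was not tested. The shuffled control holds base composition constant, while nearby windows match it only as closely as the DNA there allows. With depth unknown, no statement on a missing peak, as at per, Clk or cyc, goes beyond its absence from the list.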

Other observations

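Of the tests below, those on promoter position, on GC beside the core, on AAGTCA and on Hr51 in each replicate's own list were chosen only after their results were seen; matched gene lists were planned, but how far they may lie from the ribosomal count was set after their values were seen; mitochondrial ribosomal protein and tRNA genes were added after the lists were seen and before their own counts were. Mitochondrial ribosomal protein genes, of which mRpL41 had the fourth strongest peak, had a promoter peak in 25 of 73 cases (34.2%, 95% Wilson interval 24.4 to 45.7%), against 23.2% of other genes (Fisher's exact test, p = 0.036), with 23 in replicate 1 and 31 in replicate 3. This was fewer than the 58 of 82 cytoplasmic ribosomal protein genes (Fisher's exact test, p = 6.0e-06). Of 190 tRNA genes more than 1 kb from other kinds of TSS, 30 (15.8%) had a reproducible summit within 1 kb, against 10.1% for random places (permutation of positions, p = 0.098).

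The peaks at cytoplasmic ribosomal protein genes are not accounted for by the number of TSSs and gene length, since matched lists gave 17.3 genes on average. If expression in nearly all cells were the whole cause, mitochondrial ribosomal protein genes would have a like share, and theirs was 34.2%. How broadly or strongly either group is expressed was not measured, and the mitochondrial list was not matched on TSS number or length. This comparison therefore does not settle a role of expression. Recovery of any strongly transcribed locus, a known weakness of ChIP without a second tag or an untagged strain, cannot be told apart from binding here: the 15.8% at tRNA genes lay above random places but not past the threshold, and expression in these embryos was not analysed here. Binding by Hr51 at these promoters stays open as a hypothesis.

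The AT-rich core of Hr51 summits is not a trait of promoters alone, since away from TSSs GC content at the summit was lower than 250 bp away, by -15.2 percentage points (SE 0.213, n = 3865). Direct recognition of AAGTCA at most summits is also excluded for this form of the site: the upper 95% bound of its excess over windows of the same GC content was 1.43 percentage points. Farther than 1 kb from a TSS, DNA 200 to 400 bp from the summit was higher in GC than DNA 600 to 1000 bp away, by 4.58 percentage points (SE 0.116). Fragments near 800 bp, the longest per the labels, also hold the core when they lie over a summit. At these summits the 100 bp on each side had 33.1% GC. The flanks alone therefore do not give the GC of such fragments, and a bias of long fragments is not decided. Fragments of intermediate length were not tested. Within 1 kb of a TSS the difference in the flanks was 0.208 (SE 0.143), so such a bias stays open there too. A bias of the shortest fragments, of 200 bp, cannot be told apart from the core, because they lie inside it: the 100 bp on each side of the summit were lower than DNA 600 to 1000 bp away by -8.22 percentage points (SE 0.109). Another AT-rich recognition sequence or a partner protein was not tested.

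The peaks around the Hr51 gene do not come from 1 sample: within 20 kb, replicate 1's own list held 34 and replicate 3's own list 25, more per kb than around 99.3% and 96.2% of protein-coding genes. A candidate explanation is technical: a transgene that carries the Hr51 region adds copies of it, which raises signal over the whole stretch. Within 20 kb of Hr51 the pooled list held 29 peaks, 0.603 per kb against a median of 0.193 over protein-coding genes, more than 98.3% of them, as extra copies would give. The labels do not give the extent of the transgene, and a region rich in binding sites would also look like this, so binding of Hr51 to its own gene stays open and untested. The same doubt covers the unc-5 peak in this stretch and the place of Hr51 among the remodelling and nuclear receptor genes.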
